A study of Mus musculus with 2 samples.

How the data were processed

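The samples were 2 DNase-seq libraries of the right cerebral cortex of male B6CASTF1/J mice aged 2 months, labelled as biological replicates 1 and 2 and as animals 5 and 6. The labels give both the same donor record, so that the animals are separate rests on the animal numbers. For each library a pair of peak sets, a file of false discovery rates per base and a set of footprints were used. Per the deposited descriptions, each file was derived from that library's own filtered alignments to mm10, so peaks were called per library and not on pooled samples. The aligner, the peak caller, the footprint caller, their versions and their thresholds are not given in the sources used here. The value of each peak is a signal, the peak height, as deposited by the authors. In each library all heights were whole multiples of a step (0.00626 in replicate 1 and 0.00768 in replicate 2, within 0.02 of a step), and what the step stands for is not stated. The false discovery rate per base is a q-value deposited by the authors, listed for bases under 0.05. Every peak of the smaller set of a library held a base under 0.001, and every peak of the larger set a base under 0.05. The smaller, stricter set was used throughout. The deposited footprints carry the constant 0.01, read as the authors' p-value threshold, and no score of their own.

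In every file the names of all 21 chromosomes matched GRCm38.p6 and all coordinates lay within its chromosome lengths. Genes were taken from GENCODE M21. Depth is not given in the sources used here, so the precision of single peaks is unknown. Counting intervals cover counting error only. Overlap between peak sets meant at least 1 bp in common, and chance levels came from peaks moved at random within their chromosome. Peak centres were placed, in this order, within 1000 bp of a transcript start, in an exon, in an intron or in intergenic DNA. For X, peaks per Mb of assembled sequence, peaks per protein-coding gene and median height were compared with the 19 autosomes. Spearman's rho and Pearson's r of log10 height were computed across shared peaks.

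The 27 gene lists, the 26 consensus motifs and the rule for named genes were fixed before the data were examined. A member of a list had a promoter peak if a peak lay within 1000 bp of any of its transcript starts. The mean share of the 2 libraries was placed among 10000 random lists of protein-coding genes of the same size and gene-length deciles, and the same was done for the number of peaks in the gene body and 20000 bp on each side. A list stood apart outside the central 95% of random lists. The text names the 2 or 3 members of a list with the tallest promoter peaks in both libraries, up to 2 members with none, and those with the most peaks around them. Some genes that this rule selects are not reported here. The text also names the 10 tallest shared peaks over 10000 bp from a transcript start and the 10 tallest peaks of each library with no overlapping peak or broader region in the other. The overall tallest peaks and the genes with peaks in 1 library only were named after their values were seen. Promoter peaks are assigned by distance. For members of the gene lists, peaks near the start of another protein-coding gene are stated as such where named. The tallest shared peaks and those of 1 library only were given the nearest start, and further starts near them were not looked for.

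Footprints were extended by 5 bp on each side and searched for each consensus on both strands. Each was compared with a window of the same width placed at random in the same peak, off all footprints, which could be found for 95.7% and 98.7% of the footprints inside peaks. Footprints without such a window were left out of the motif counts. Ratios have exact 95% counting intervals. Copy number in the assembly is the median count of 3 words of 31 bases per peak, on both strands, over all chromosomes and unplaced sequence. Peak overlap, peak counts, random gene lists, motif matching, copy number, height steps and emptied windows were first tested on simulated data. Location classes, the comparisons of X, footprint overlap, the placing of control windows and height ratios around gene lists were not. All 500 planted overlaps among 2000 peaks, all 5200 planted motifs and the copy number of all 50 planted repeats were recovered. Of 200 gene lists drawn at random 5 fell outside the central 95%, and all 200 lists with a peak set at every member lay above it. The simulated peaks fell on genes regardless of their length, so the matching on length was not tested. Windows of 50000 bp emptied on purpose were found 30 of 30 times. With 1 group of 2 libraries no p-value was computed, and results are values per library or means with their SD. The alternatives covered the overlap rule, the peak set, the promoter window, the flank, the matching of random lists, the control for motifs and each library left out, with their effect in the closing section. Reads and coverage were not analysed here. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.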

Results

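DNase-seq maps open chromatin by sequencing the places where the nuclease DNase I cuts DNA in nuclei, so a peak marks a region that was accessible to the enzyme. The tissue was the right cerebral cortex of male B6CASTF1/J mice, a first-generation cross of C57BL/6J and CAST/EiJ, at 2 months of age. There was 1 group with 2 biological replicates, and the labels number the animals 5 (replicate 1) and 6 (replicate 2), so each library is read here as 1 animal. With a single group there was no contrast to test. The question addressed was which parts of the genome were accessible in this tissue and how well the 2 libraries matched. Replicate 1 had 91818 peaks in the stricter of its peak sets and replicate 2 had 75245. These peaks had a median width of 200 bp in both libraries, and they covered 19.6 Mb and 15.4 Mb. The broader sets held 162420 and 131881 peaks. Bases with a false discovery rate under 0.05 covered 56.7 Mb in replicate 1 and 42.6 Mb in replicate 2, of which 35.3 Mb were common to both. The sequencing depth is not given in the sources used here, and peak height is the authors' value in units whose scaling is not stated, so heights are compared mainly within a library.

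Open chromatin was concentrated at gene starts. A mean of 32.6% ± 0.464 (SD, n = 2) of peak centres lay within 1000 bp of an annotated transcript start, against 6.27% and 6.28% for peaks placed at random on the same chromosomes. Introns held 32.3% ± 0.486 (SD, n = 2), intergenic DNA 31.1% ± 1.43 (SD, n = 2) and exons 3.97% ± 0.483 (SD, n = 2). Intergenic DNA was underrepresented, since random placement put 50.3% and 50.2% of peaks there. Promoter peaks were also taller, with median heights of 1.31 and 1.14 in replicates 1 and 2, against 0.820 and 0.722 for peaks farther from a start. Of 21938 protein-coding genes, 63.4% had a promoter peak in replicate 1, 59.3% in replicate 2 and 58.7% in both. Olfactory receptor genes, which are used in sensory neurons of the nose, formed the opposite extreme: 24 (2.11%) and 22 (1.94%) of their 1135 members had a promoter peak.

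The tallest shared peak lay on chromosome 17 from 39846781 to 39846920 (mm10), 107 bp from the start of the noncoding gene Gm42418, with heights of 65.5 and 49.8. The third tallest fell in an exon of Lars2, the mitochondrial leucyl-tRNA synthetase gene, on chromosome 9 from 123461881 to 123462140, at 37.1 and 30.9. An intron of Il31ra, which encodes a cytokine receptor subunit, held another on chromosome 13 from 112578141 to 112578340, at 26.3 and 21.1. Each of these 3 sequences occurred in 2 copies in the reference assembly by its 31-base words. By mean height the tallest single-copy peak stood 10 bp from the start of Trpm8, the cold and menthol receptor gene. It lay on chromosome 1 from 88277541 to 88277760, at 18.6 and 14.2. In replicate 2 the Cers5 peak named next was taller. Among peaks over 10000 bp from any transcript start, the tallest single-copy one was in an exon of the ceramide synthase gene Cers5, on chromosome 15 from 99735661 to 99736060, at 16.4 and 15.4. An intronic peak of Gphn, which encodes the inhibitory synapse scaffold gephyrin, followed on chromosome 12 from 78350861 to 78351100, at 14.6 and 10.97. Farther down stood an intergenic peak 72645 bp from the start of Irf2bp2, a transcriptional corepressor gene, on chromosome 8 from 126666501 to 126666760, at 8.62 and 5.60. Another, on chromosome 6 from 47650741 to 47651000, lay 55530 bp from the start of Ezh2, the histone methyltransferase of the Polycomb system, with 46.9% of its bases marked as repeated, at 8.75 and 6.16. The other 6 of these 10 distal peaks were in introns of Mid1, a ubiquitin ligase gene on X that held 2 of them, in an intron of the Polycomb cofactor gene Jarid2, and in intergenic DNA nearest to Gm25352, Gm43980 and Gm20281. All of those except the Gm20281 peak had 2 or more copies in the assembly.

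The strongest accessible sites were found in both animals, and the weaker ones differed. Of the peaks of replicate 1, 66.2% overlapped a peak of replicate 2 by at least 1 bp, and 80.8% of the peaks of replicate 2 overlapped one of replicate 1. Placing peaks at random gave 1.22% and 1.48%. In the highest decile of peak height the shares were 99.3% and 99.9%, and in the lowest decile 25.7% and 42.5%. Promoter peaks were found more often, at 71.1% and 88.7%, than distal ones, at 63.8% and 77.0%. Across the 60789 shared peaks, heights had a Spearman's rho of 0.910 and a Pearson's r of 0.925 on a log10 scale, where peaks within a library are not independent replicates. The median ratio of replicate 1 over replicate 2 was 1.38, and 2.27% of pairs lay more than 2-fold from it. The base-pair Jaccard index was 0.472.

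**Figure D1:**
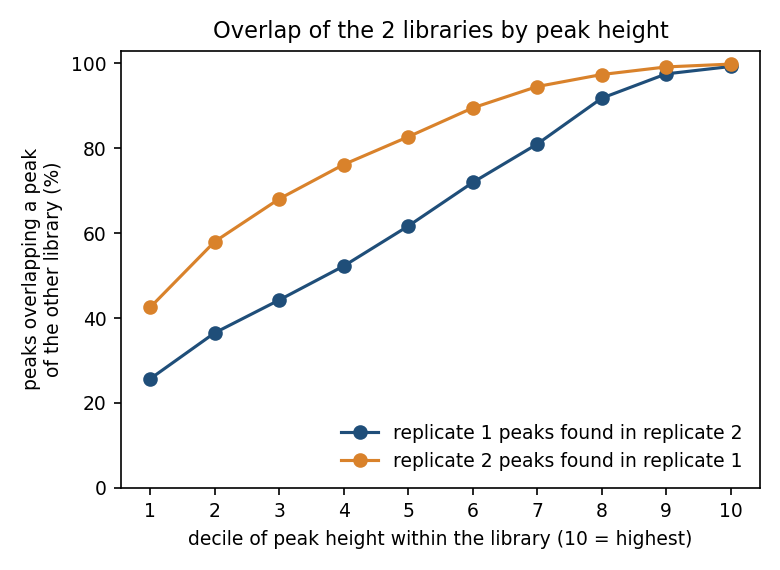
Share of peaks that overlap a peak of the other library, in percent, by decile of peak height within each library, with 1 point per library and decile. The shares climb from 25.7% and 42.5% in the lowest decile to 99.3% and 99.9% in the highest.

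The tallest peaks with no overlapping peak or broader region in the other library were at promoters in 19 of 20 cases. In replicate 1 they were led by Osbp, an oxysterol-binding protein gene (9.29), followed by the calmodulin-binding transcription activator gene Camta1 (6.30), Napa, which encodes a SNARE recycling factor (5.61), and Txndc9 (4.98). Polr2b, an RNA polymerase II subunit gene (4.82), and the transcription factor gene Atf2 (4.62) were among the others, with Ubtd1, Map3k10, Brat1 and Ddx39. In replicate 2 the first was again at Osbp (6.00), followed by the COP9 signalosome gene Cops7b (3.45), Rpp38, an RNase P subunit gene (3.11), and Rnf44 (2.67). The immediate early gene Egr1 (2.64) was there too, besides Ttc32, Mamdc4, Supv3l1, Tsen34 and an intergenic site 6635 bp from Snord12. At Osbp the peaks were direct neighbours on chromosome 19, from 11965541 to 11965780 in replicate 1 and from 11965221 to 11965540 in replicate 2. All 20 of these peaks lay within 100 bp of a peak of the other library, as did 6.44% and 9.68% of all peaks with no counterpart (no overlapping peak in the other library). In each of the 20 the other library listed bases, with a lowest false discovery rate of at most 1.12e-11, the value at Map3k10. These 20 sites were thus accessible in both libraries, and their called peaks did not overlap. Of all 31029 and 14441 peaks with no counterpart, 64.9% and 76.1% touched bases that the other library listed at a false discovery rate under 0.05.

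Promoters of pan-neuronal and synaptic genes were open in both animals. The list of pan-neuronal and synaptic genes had a promoter peak at 14 and 13 of its 14 members in replicates 1 and 2, placing its mean at percentile 99.7 of 10000 random lists matched on gene length. Vamp2, the synaptic vesicle fusion protein gene, led it with heights of 4.42 and 2.56, followed by Syt1, the calcium sensor of transmitter release (3.06 and 2.23), and the neuronal tubulin gene Tubb3 (2.98 and 2.12). Markers of cortical excitatory neurons had promoter peaks at 12 and 8 of 12 members (percentile 94.6), among them Camk2a, a postsynaptic kinase gene (3.59 and 2.62), and Nrgn, which encodes a calmodulin-binding postsynaptic protein (3.02 and 1.95). All 11 deep-layer markers had one in replicate 1 and 8 in replicate 2 (percentile 91.0), with the corepressor gene Tle4 highest at 9.91 and 7.03 and Pcp4, another calmodulin regulator gene, at 4.42 and 2.66. Upper-layer markers had one at 9 and 7 of 9 members (percentile 89.8), including the POU factor gene Pou3f3 (4.40 and 3.31) and Rorb, a nuclear receptor gene of layer 4 (2.80 and 1.77). In replicate 1 alone these 3 cortical lists lay above the central 95% of random lists, and in the mean of both libraries they lay inside it. Their percentiles in replicate 1 were 99.8 for excitatory, 98.8 for deep-layer and 97.505 for upper-layer markers, the last at the edge of the range. The excitatory and deep-layer lists share Tbr1 and Fezf2, which had no promoter peak in replicate 2, so these lists are not independent.

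Every member of 3 lists had a promoter peak in both libraries. These were the immediate early genes, which neurons switch on within minutes of activity (15 of 15, percentile 100), the circadian clock genes (12 of 12, percentile 99.9) and the housekeeping genes (15 of 15, percentile 99.99). Among immediate early genes, the promoter of Jun, an AP-1 subunit gene, reached 11.2 and 7.29, and that of Egr1 6.65 and 3.85. The clock repressor genes Per1, at 11.5 and 7.42, and Nr1d1, at 9.26 and 6.64, had the tallest promoter peaks of their list. Tbp, the TATA-binding protein gene, reached 7.41 and 4.76 at a promoter it shares with the proteasome gene Psmb1, and the ribosomal protein gene Rpl13a 7.53 and 6.14. The peak of Per1 lay on chromosome 11 from 69094781 to 69095180 in replicate 1, just upstream of the gene, and that of Jun on chromosome 4 from 95052161 to 95052420 in both.

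Inhibitory neuron, astrocyte, oligodendrocyte and precursor markers had shares of open promoters inside the central 95% of random lists, and microglial markers lay below it. Among the higher-scoring 50% of peaks the inhibitory neuron list also lay below it, at percentile 0.140. Inhibitory neuron markers had a promoter peak at 7 and 6 of 14 members (percentile 18.7): Adarb2, a gene of the adenosine deaminase family found in interneurons, stood at 1.45 and 1.29, Gad1, the GABA-synthesizing enzyme gene, at 1.11 and 1.11, and the calcium buffer gene Pvalb at 0.726 and 0.614, and the homeobox genes Dlx5 and Dlx6 had none. Astrocyte markers had one at 10 and 7 of 12 members (percentile 74.3), including Sox9, a glial transcription factor gene (2.11 and 1.51), the intermediate filament gene Gfap (2.02 and 1.14) and Aldoc (1.90 and 1.07), whereas the water channel gene Aqp4 and Aldh1l1 had none. Of 13 oligodendrocyte markers, 6 and 5 had one (percentile 5.67), with Mbp, a myelin protein gene, at 1.49 and 1.14, Olig1, a lineage transcription factor gene, at 1.53 and 1.03, and Cnp at 1.37 and 0.952, while Mag and Cldn11 had none. Precursor cell markers had one at 4 and 5 of 9 members (percentile 14.9), among them Vcan (1.75 and 1.65) and the growth factor receptor gene Pdgfra (1.70 and 1.29), while the proteoglycan gene Cspg4 and the receptor gene Gpr17 had none. Microglial markers had one at 3 and 1 of 13 members (percentile 0.030), and the complement genes C1qa and C1qb had none.

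Among markers of blood vessels and brain coverings, endothelium and mural cells lay below the central 95% of random lists at promoters, and choroid plexus and meninges lay inside it. Meninges also lay below it without replicate 1 (percentile 1.16) and among the higher-scoring 50% of peaks (percentile 0.675). Brain endothelium had a promoter peak at 6 and 3 of 12 members (percentile 0.95), with the glucose transporter gene Slc2a1 at 2.35 and 1.54 and the ETS factor gene Erg at 0.638 and 0.438, and none at the junction gene Cdh5 or the forkhead gene Foxq1. The call for endothelium was lost without replicate 2 (percentile 7.10), with a 2500 bp window, with the 5-prime end of the gene only (percentile 3.57) and without length matching (percentile 4.31). Mural cells had 3 and 1 of 9 (percentile 0.270), with the potassium channel gene Kcnj8 at 0.607 and 0.315 and none at the smooth muscle actin gene Acta2 or at Abcc9. Choroid plexus and ependyma had 4 and 2 of 8 (percentile 9.42), with none at the water channel gene Aqp1 or at Clic6, and meninges 4 and 2 of 9 (percentile 3.29), with none at the collagen gene Col1a2. Taller promoter peaks stood at the ciliogenesis factor gene Foxj1, an ependymal marker (6.25 and 3.68), and at the collagen gene Col1a1 among meningeal markers (2.93 and 1.60), ahead of the ciliary gene Ccdc153 (1.10 and 0.791) and the proteoglycan gene Dcn (0.332 and 0.292).

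Genes of most other organs were rarely open at the promoter. None of the 15 Hox genes, which pattern the hindbrain and trunk, and none of the 13 liver genes had a promoter peak in either library, among them Hoxa2, Hoxa10, the albumin gene Alb and Ahsg. Lymphoid genes had 2 and 2 of 14 (percentile 0.025), with the T-cell kinase gene Lck at 1.59 and 1.04 and none at the antigen receptor gene Cd3d. Germ cell genes had 2 and 2 of 12 (percentile 0.075), with the RNA-binding protein gene Dazl at 1.45 and 0.914 and none at Ddx4 or Mael. Striated muscle had 4 and 3 of 15 (percentile 0.495, but 6.79 and inside the random range with a 2500 bp promoter window), with the creatine kinase gene Ckm at 2.42 and 1.27 and none at the actin gene Acta1 or the myoglobin gene Mb. The actinin gene Actn3 stood at 4.71 and 3.20, but that peak was also near the start of Zdhhc24. Erythroid genes had 2 and 3 of 10 (percentile 0.655), with the erythropoietin receptor gene Epor at 1.73 and 1.34, and none at Alas2 or Epb42; without replicate 1 that list was inside the random range, at percentile 2.88. Epidermis genes had 3 and 3 of 9 (percentile 14.7), with the keratin genes Krt10 at 2.58 and 1.91 and Krt1 at 1.21 and 0.768, and none at Ivl or Dsg3.

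Among markers of other brain regions, those of thalamus and hypothalamus lay below the central 95% of random lists, and those of striatum, cerebellum and midbrain lay inside it. Thalamus and hypothalamus markers had 4 and 3 of 12 (percentile 2.33), led by the orexin gene Hcrt at 3.599 and 2.08 and the feeding peptide gene Agrp at 2.60 and 1.81, although the Agrp peak also lay at the start of Ctcf. The homeobox gene Gbx2 and the vasopressin gene Avp had none, and without replicate 2 this list lay inside the random range, at percentile 4.54. Cerebellum and midbrain markers had 4 and 2 of 10 (percentile 10.5), with the synaptic organizer gene Cbln1 at 2.20 and 1.51, Cbln3 at 2.02 and 1.29 by a peak also near another coding gene, and none at the homeobox genes Barhl1 and En1. Striatum markers had 6 and 6 of 10 (percentile 48.0), with the signalling regulator gene Rgs9 at 3.61 and 2.23 and the dopamine receptor gene Drd1 at 2.77 and 1.34, and none at Drd2 or the homeobox gene Isl1. Imprinted genes, expressed from 1 parental copy, had 12 and 11 of 15 (percentile 86.7), including the noncoding RNA gene Kcnq1ot1 at 6.20 and 3.57 and the zinc finger gene Peg3 at 3.58 and 2.29 by a peak also near the start of Usp29, but the noncoding RNA gene H19 and the growth factor gene Igf2 had none. In all, 4 lists lay above the central 95% of random lists and 10 below it. Random lists compare genes within these libraries and are not a test across animals.

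**Figure D2:**
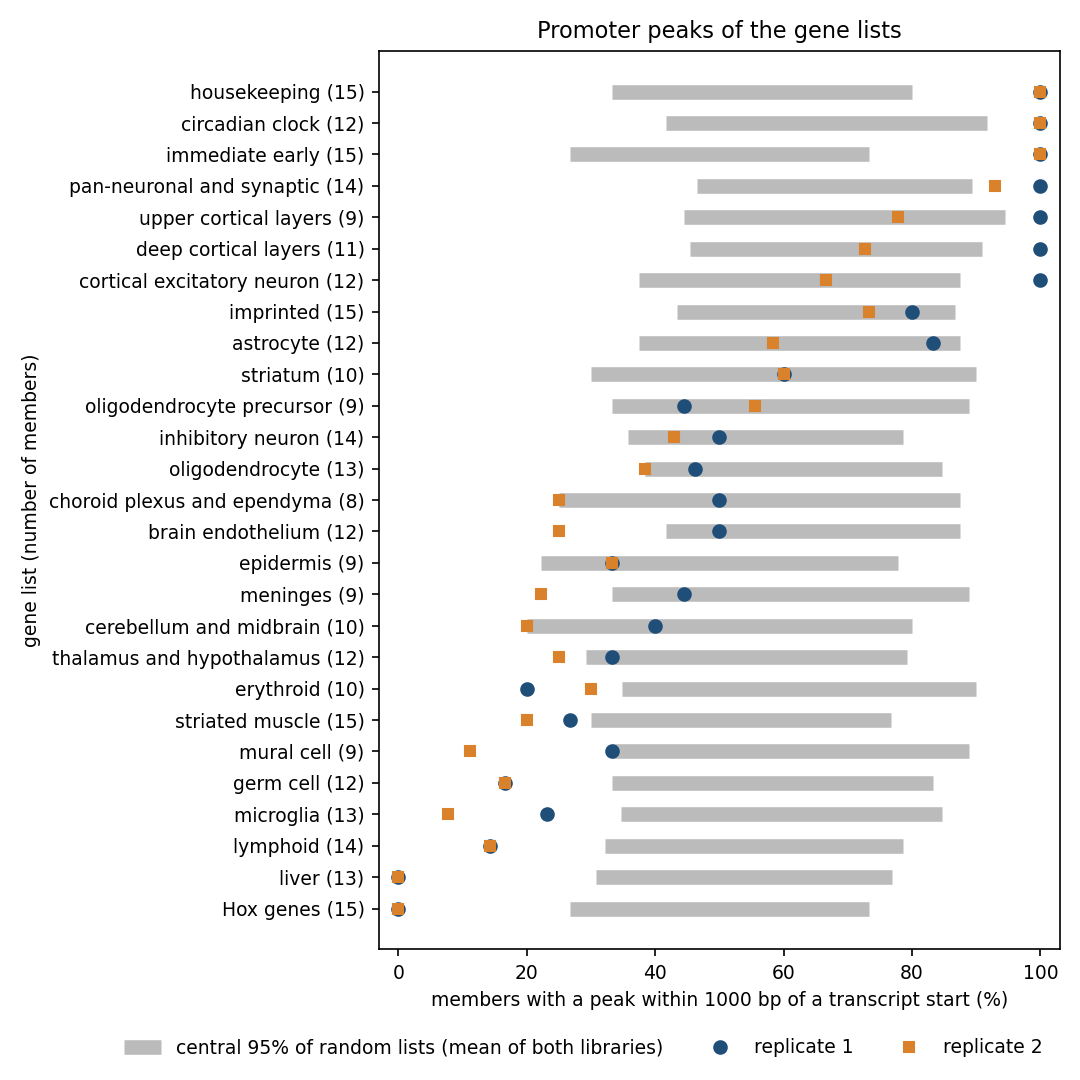
Share of each list's members with a peak within 1000 bp of a transcript start, in percent, for replicate 1 (circles) and replicate 2 (squares). Grey bars give the central 95% of 10000 random lists of the same size matched on gene length; the immediate early, clock and housekeeping lists are at 100% in both libraries, and the Hox and liver lists are at 0% in both.

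In the mean of the libraries, peaks in and around genes were most numerous for immediate early and clock genes, and the libraries differed around markers of excitatory and upper-layer neurons. Counting peaks in the gene body and 20000 bp on each side, immediate early genes had medians of 11 and 8 in replicates 1 and 2 (percentile 100), clock genes 9 and 8 (percentile 99.995) and pan-neuronal genes 8 and 6 (percentile 98.5). These 3 lists lay above the central 95% of random lists and none lay below it, though the pan-neuronal list was inside it without replicate 1 (percentile 95.9), with gene bodies only (percentile 93.7) and with peaks over 1000 bp from a start (percentile 92.01). Nr1d1 had 26 and 24 peaks, Per1 23 and 14, the neuronal splicing factor gene Rbfox3 28 and 24, Syt1 26 and 7, Egr1 18 and 10, and the AP-1 gene Fosb 17 and 12. Excitatory neuron markers had medians of 9.5 and 3 (percentile 95.04) and upper-layer markers 14 and 2 (percentile 93.7). Excitatory markers lay above the central 95% of random lists with gene bodies only (percentile 99.8), with peaks over 1000 bp from a start (percentile 98.3), without length matching (percentile 97.7) and without replicate 2 (percentile 99.8), and upper-layer markers did without length matching (percentile 99.5). For upper-layer markers each library on its own gave opposite results, percentile 99.9 in replicate 1 and percentile 2.06 in replicate 2. The difference between the libraries, 6.5 peaks for excitatory markers and 12 for upper-layer markers, lay at percentiles 99.995 and 100 of the same difference in random lists. This difference was taken up after the lists were seen, so its percentiles describe it and do not test it. It was still 6.5 and 9 with both libraries at 75245 peaks, a comparison also chosen after the data were seen. There epidermis genes differed the other way, by -2 peaks (percentile 1.29). The immediate early list also had an excess in replicate 1, of 3 peaks (percentile 98.9). The glutamate receptor gene Grin2b had 23 and 10 peaks, the homeobox genes Cux1 and Cux2 of upper layers 28 and 18 and 22 and 11, and among deep-layer genes Bcl11b 19 and 6 and Sox5 31 and 25.

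Some of these genes had many peaks in replicate 1 and none in replicate 2, and others, such as Pou3f3 with 12 and 1, had few. Around Pou3f2, a POU factor gene of upper-layer neurons (chromosome 4 from 22482780 to 22488366), replicate 1 had 24 peaks and 13627 bases at a false discovery rate under 0.05, and replicate 2 had 0 peaks and 64 such bases. Nrn1, which encodes the neuronal surface protein neuritin (chromosome 13 from 36725361 to 36735131), had 18 peaks and 10631 bases against 0 and 0. Tbr1, a T-box gene of deep-layer neurons (chromosome 2 from 61802930 to 61814114), had 15 peaks against 0, and Fezf2, a zinc finger gene of subcerebral projection neurons (chromosome 14 from 12342094 to 12348189), had 11 against 0. Mef2c, a transcription factor gene of excitatory neurons, had more peaks in replicate 2, with 7 and 10, and Camk2a had 14 and 9. Pou3f2, Nrn1, Tbr1, Fezf2 and Mef2c were chosen after their values were seen. Coverage was not analysed here, so whether signal at such genes was absent from replicate 2 or was present and not called is open. Peaks in the 50000 bp windows that only replicate 1 filled had a low median height, 0.407 against 0.932 for all its peaks. Not all of them were weak, since the highest stood at 2.53. The windows of Tbr1, Pou3f2 and Nrn1 reached 2.41, 1.73 and 1.68.

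The other lists had numbers of peaks around their genes that lay inside the central 95% of random lists, though some left it with other choices. With peaks over 1000 bp from a start, oligodendrocyte (percentile 99.1) and epidermis genes (percentile 97.7) lay above it, and with gene bodies only imprinted (percentile 98.7) and housekeeping genes (percentile 98.3) did. Housekeeping genes also did without replicate 1 (percentile 98.2), and endothelium lay below it among the higher-scoring 50% of peaks (percentile 0.200). Deep layers had medians of 7 and 5 (percentile 76.8), inhibitory neurons 4 and 2.5 (percentile 34.3), astrocytes 5 and 3.5 (percentile 59.3), oligodendrocytes 5 and 3 (percentile 58.6), their precursors 5 and 5 (percentile 65.6) and microglia 3 and 3 (percentile 27.7). Among these, the receptor gene Erbb4 and the homeobox gene Dlx1 of interneurons had 12 and 14 and 8 and 10 peaks, the glutamate transporter gene Slc1a2 10 and 10, Aldh1l1 10 and 13, and Mbp 16 and 12. Around the microglial chemokine receptor gene Cx3cr1 there were 20 and 14 peaks, although its promoter had none. Endothelium had 3.5 and 3 (percentile 8.80), mural cells 4 and 3 (percentile 28.6), choroid plexus 2 and 1.5 (percentile 6.25) and meninges 2 and 1 (percentile 3.19). Imprinted genes had 6 and 4 (percentile 81.1), striatum 3 and 3 (percentile 21.6), cerebellum and midbrain 3 and 1 (percentile 24.7), and thalamus and hypothalamus 2.5 and 1 (percentile 6.70). Hox genes had 2 and 2 (percentile 22.5), liver 3 and 3 (percentile 40.1), muscle 4 and 3 (percentile 68.5), erythroid 4 and 3 (percentile 45.3), lymphoid 4 and 3.5 (percentile 64.3), germ cell 3 and 2.5 (percentile 24.05) and epidermis genes 4 and 4 (percentile 74.6). Housekeeping genes had 5 and 5 (percentile 96.4), with 20 and 14 around the glycolytic gene Gapdh. Around the T-cell coreceptor gene Cd4 there were 17 and 18.

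**Figure D3:**
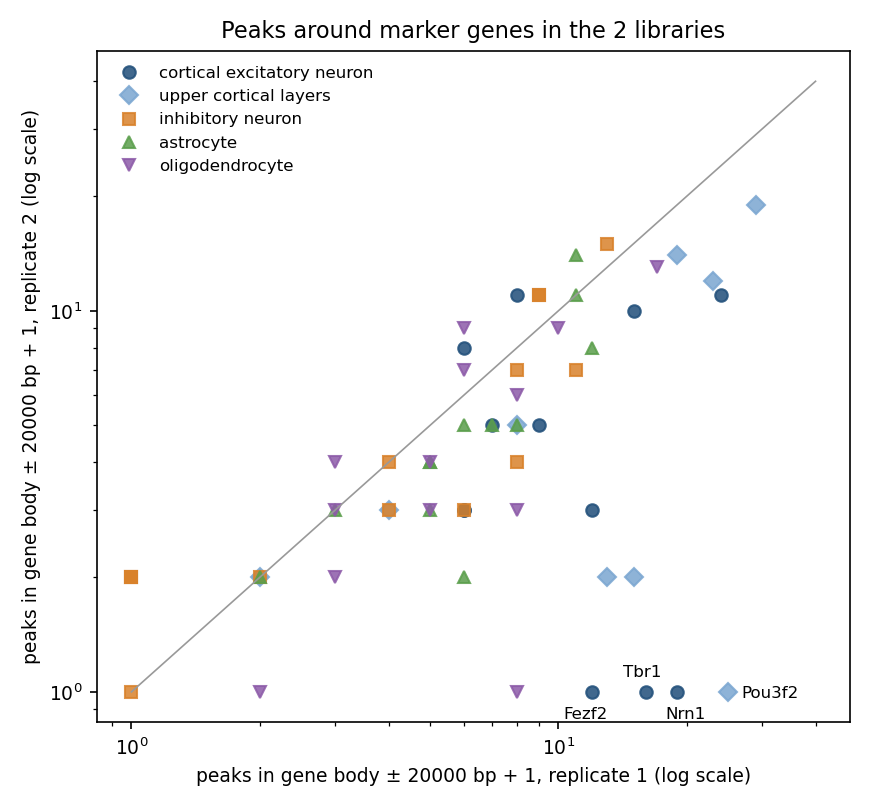
Number of peaks in the gene body and 20000 bp on each side, plus 1, in replicate 1 (horizontal) and replicate 2 (vertical), both on log scales, for members of 5 marker lists, with the line of equal numbers. Pou3f2, Nrn1, Tbr1 and Fezf2 have 24, 18, 15 and 11 peaks in replicate 1 and 0 in replicate 2.

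The X chromosome, present in 1 copy in males, was the least accessible of the 20 chromosomes compared. It had 13.9 and 12.7 peaks per Mb of assembled sequence in replicates 1 and 2, while the autosomes had medians of 37.4 and 30.3 and none was below 29.4 and 25.7 (chromosome 14 in both). The ratio of X to the autosome median was 0.395 ± 0.0322 (SD, n = 2), a difference much larger than the spread between the animals. Per protein-coding gene the ratio was 0.555 ± 0.0383 (SD, n = 2). Peaks on X were also lower, with a median height of 0.624 ± 0.0127 (SD, n = 2) of the autosome median. Promoter peaks were found at 47.5% and 42.7% of the protein-coding genes on X, against medians of 66.2% and 62.5% on autosomes. X ranked lowest in both libraries for peaks per Mb and height. Per gene it was clearly lowest in replicate 1, at 2.40 peaks against 2.88 on chromosome 7, but in replicate 2 the values, 2.18 and 2.20, were within counting error, with a ratio of 0.995 (95% counting interval 0.944 to 1.05). With peaks over 1000 bp from a start, X in replicate 2 had 1.37 peaks per gene, above chromosome 7 at 1.33. Among the higher-scoring 50% of peaks the density ratio fell to 0.210, but the median height on X was 0.981 and 0.926 of the autosome median, and in replicate 1 X ranked 5 from the lowest. Chromosome 11, the most densely covered, had 53.2 and 41.0 peaks per Mb, and Y had 0.306 and 0.170.

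**Figure D4:**
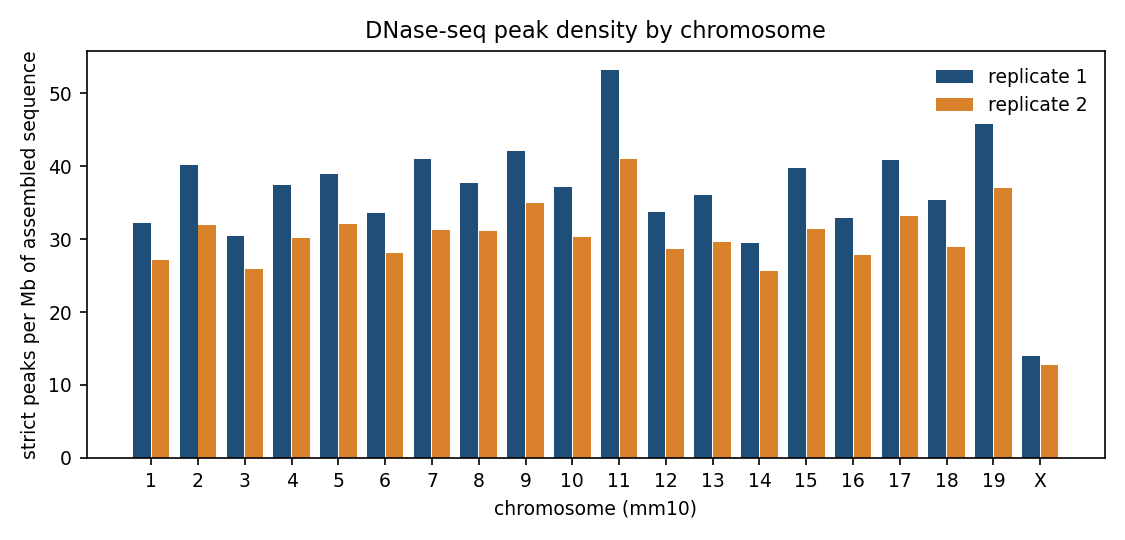
Strict peaks per Mb of assembled sequence for each autosome and X in replicate 1 and replicate 2, 1 bar per library. X has 13.9 and 12.7 peaks per Mb, below each autosome in both libraries.

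Footprints are short stretches inside open chromatin that are protected from the nuclease. A small share of them carried the recognition sequences of CTCF and of promoter-binding factors. Shares are of the footprints inside peaks for which a control window was found. In replicates 1 and 2 the CTCF consensus was in 1.41% and 2.36% of them, and that of NRF1 in 0.136% and 0.193%. This condition left out CTCF matches in replicate 1, where 3869 footprints had a match with no extension and 3357 with it. The shares and counts, and their gap between the libraries, depend on this condition. CTCF, the insulator protein, had the clearest enrichment: its consensus was in 3357 and 3917 footprints against 17 and 25 control windows of the same peaks, a ratio of 197 (95% counting interval 123 to 339) and 157 (106 to 242). NRF1, an activator of genes for mitochondrial function, had 324 and 320 matches against 1 and 4 in controls, which gave ratios of 324 (57.7 to 12836) and 80.0 (30.9 to 295). The X-box of RFX factors, regulators of ciliary genes, was in 90 and 85 footprints and in 0 control windows, at least 30-fold and 28.3-fold higher against a floor of 3 counts per library. EGR sites had ratios of 24.2 and 22.8, cyclic AMP response elements 21.1 and 25.04, and SP/KLF sites 12.1 and 7.85. The palindrome of NFI factors, which act in glia and neurons, was in 46 footprints against 1 control window in replicate 1, a ratio of 46.0 (7.85 to 1856), and in 28 against 0 in replicate 2, at least 9.33-fold.

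The order of the motifs depended on the comparison. Against the reversed consensus in the same footprints, CTCF in replicate 1 stood at 1119, NRF1 at 162 and NFI at 23. In replicates 1 and 2, NEUROD-type sites were 28.2 and 30.98 times as frequent as their reversed consensus, MEF2 sites 14.7 and 13.5 times, cyclic AMP response elements 7.58 and 6.38 times, AP-1 sites 5.98 and 5.89 times and EGR sites 3.66 and 4.74 times. Against control windows, the E-box type bound by NEUROD factors, which drive excitatory neuron differentiation, had ratios of 3.44 and 4.54, and AP-1 sites 2.06 and 2.19. ETS sites stood at 2.44 and 3.45, YY1 at 2.46 and 2.59, CEBP at 3.67 and 2.00, and REST, the repressor of neuronal genes in other tissues, at 2.25 (0.931 to 5.98) and 4 (0.798 to 38.7), the latter from 2 control matches. MEF2 (1.10 and 1.23), ROR (1.10 and 1.16) and PU.1 (1.02 and 0.978) sites had intervals that include 1, and T-box sites (1.11 and 1.54) stood above 1 beyond the interval in replicate 2 only. Sites of GATA factors, which act in blood, were depleted at 0.368 and 0.473, as were homeobox sites (0.528 and 0.708), POU octamers (0.543 and 0.699) and TEAD sites (0.653 and 0.733). SOX (0.856 and 0.714) and RUNX (0.844 and 0.829) were below 1 with intervals that include it. SRF (0.621 and 1.73) and HNF4 (1.30 and 0.571) also had intervals that include 1 in both libraries, and HNF1 had 1 match in replicate 1 and 0 in replicate 2. Besides RFX and NFI, which had 0 control matches in 1 library or more, 14 of the 26 motifs had a ratio above 1 in both libraries, and 6 had a ratio below 1 in both. Footprints were richer in G and C (59.5% and 58.0%) than their controls (53.1% and 52.9%), and the GATA, homeobox and POU sequences are rich in A and T. Compared with the reversed consensus in the same footprints, SOX, POU, homeobox, TEAD and RUNX had ratios above 1, and GATA stayed below it at 0.812 and 0.688. Reversal keeps base composition but changes which bases are neighbours. This comparison therefore cannot separate enrichment in footprints from how common a sequence is elsewhere. The POU ratios rested on 7 and 3 reversed matches, and the MEF2 ratios on 3 and 4.

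**Figure D5:**
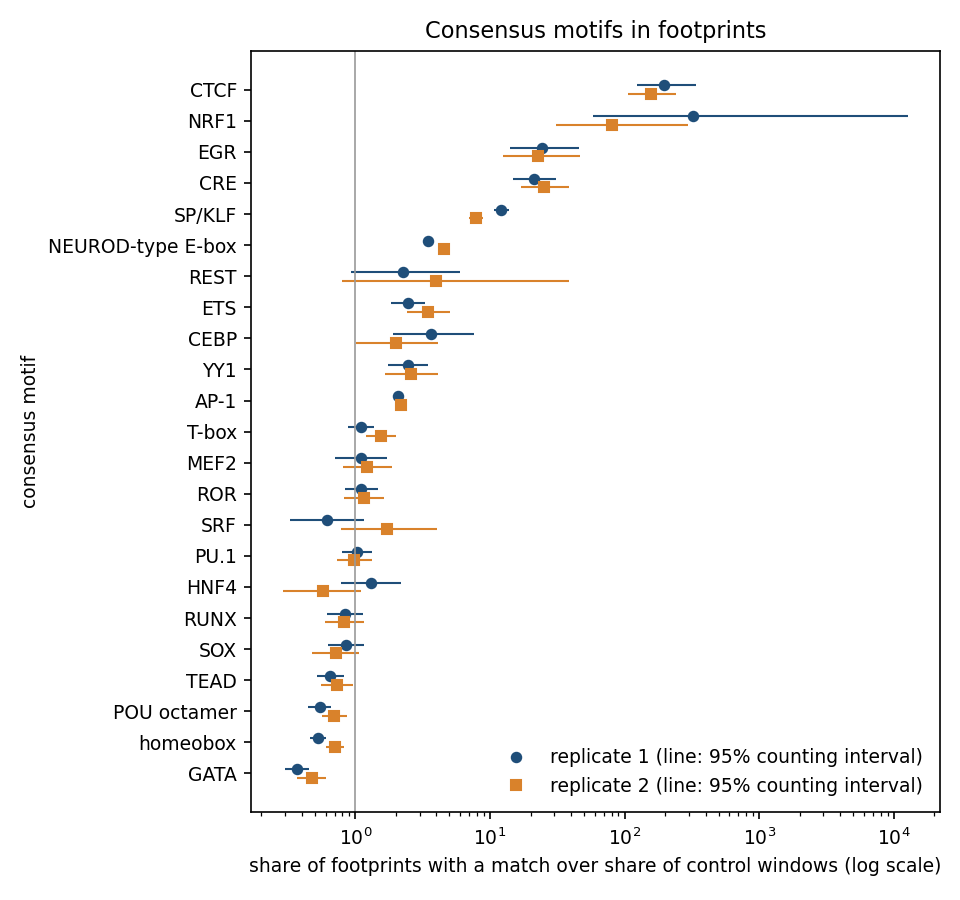
Share of footprints with a match to each consensus over the share of control windows, on a log scale, for replicate 1 (circles) and replicate 2 (squares), with 95% counting intervals as lines; motifs with 0 control matches in a library are left out. CTCF has ratios of 197 and 157 and GATA of 0.368 and 0.473.

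A lower share of footprints than of peaks was found in the other library. There were 394531 footprints in replicate 1 and 241645 in replicate 2, with a median width of 9 bp, and 30.6% and 53.4% of them overlapped a footprint of the other library. Among footprints inside peaks the shares were 40.7% and 62.6%, against 27.2% and 39.2% for footprints moved at random within their peaks. Of the strict peaks, 86.0% and 83.3% held a footprint. Replicate 1 had 6.96 footprints per kb of listed bases against 5.68 in replicate 2.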

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

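The difference between replicates around gene lists, and its comparison with both libraries at the same number of peaks, were chosen after the data were seen. The other alternatives were planned. Of 602 alternative values, 476 stayed the same by their rule. The share of peaks found in the other library, 66.2% and 80.8%, became 52.4% and 63.9% with reciprocal overlap of 50% of each peak, 74.1% and 89.6% for the higher-scoring 50% of peaks, 74.2% and 74.3% with the same number of top peaks, and 63.3% and 78.2% with the broader sets. Spearman's rho became 0.922 with reciprocal overlap and 0.860 for autosomal distal peaks. Promoter and intergenic shares were 41.0% and 28.9% with a 2500 bp window, 42.9% and 24.7% for the higher-scoring 50%, and 29.1% and 38.1% with protein-coding genes only. The X ratio was 0.352 for distal peaks, 0.210 for the higher-scoring 50% and 0.555 per gene. Footprint sharing was 20.2% and 32.9% with reciprocal overlap, and 50.8% and 68.8% inside peaks of both libraries. Taking only the better-scoring footprints was not run, since they carry no score.

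Without replicate 2, 7 lists lay above the random range at promoters, against 4 with both. Around genes, 3 lists lay above it and 0 below; with gene bodies only these were 5 and 0, with distal peaks 5 and 0, without length matching 5 and 0, with 100000 bp on each side 0 below, for the higher-scoring 50% 1 below, and with either replicate left out up to 5 above and 0 to 1 below. Upper cortical layers fell to percentile 2.06 without replicate 1 and stood at 99.9 without replicate 2. Single lists changed their side of the range at promoters in 22 of 189 alternatives (with a 2500 bp window, brain endothelium at 16.5, thalamus and hypothalamus at 5.37 and erythroid genes at 3.72 came inside it; choroid plexus at 1.04, cerebellum and midbrain at 1.68 and epidermis at 0.960 left it with 250 bp, meninges at 1.93 with 2500 bp, and inhibitory neurons at 0.140 with the higher-scoring 50% of peaks), and around genes in 16 of 189. Of the motifs, 6 were below 1 in both libraries and 1 against the reversed consensus, where SOX (1.76), POU (36.5), homeobox (1.59), TEAD (5.15) and RUNX (1.74) turned. For SP/KLF the reversed consensus is the same sequence, so it was not compared. Some ratios grew with no extension of the footprints. CTCF then stood at 3869 and 1218 in replicates 1 and 2, from 1 and 3 control matches. Cyclic AMP response elements stood at 47.7 and 112, EGR at 57.6 and 37.8 and SP/KLF at 29.2 and 18.8. MEF2 turned to 0.744 and ROR to 0.791 with no extension, and ROR to 0.870 in footprints of both libraries; the cause was not tested for these or for the other changes. No paired analysis was possible because there is only 1 group.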

Other observations

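The tests of promoters on X, of genes and copy number together, of the excitatory neuron share, of whole windows and of the separate ranks of the tallest peaks were chosen only after the result was seen.

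Some genes had many peaks in 1 library and none in the other. Of protein-coding genes with 8 or more peaks in and around them in replicate 1, 14 of 4994 had none in replicate 2. Besides Pou3f2, Nrn1, Tbr1 and Fezf2 they were the homeobox genes Otx1 (20 peaks), Irx2 (17), Otp (11) and Alx4 (8), the neuroendocrine factor gene Insm1 (10), Foxd3 (11), Sox14 (10), the T-box gene Tbx18 (11), and the secreted factor genes Wnt5a (12) and Inhba (9). In the other direction there were 4 of 2905, namely the neural progenitor gene Sox1 (16), the endoderm factor gene Foxa1 (8) and the olfactory receptor genes Olfr90 and Olfr91 (10 each). At Otx1, on chromosome 11 from 21994764 to 22002897, replicate 1 listed 11843 bases under a false discovery rate of 0.05 and replicate 2 listed 0. At Sox1, on chromosome 8 from 12395295 to 12400126, the numbers were 420 and 8712.

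Peaks seen in 1 animal also differed in base composition. Distal peaks of replicate 1 with no counterpart had 50.5% G and C, those of replicate 2 had 44.4% and shared ones 49.9%. Of replicate 2 peaks with under 40% G and C, 40.4% were found in replicate 1, against 93.5% of those with 60% or more, whereas the same groups of replicate 1 peaks were found at 72.9% and 75.2%. SP/KLF sites were 3.26 times (95% interval 2.31 to 4.61) and EGR sites 3.94 times (1.68 to 9.23) as frequent in the distal peaks of replicate 1 only as in those of replicate 2 only. MEF2 sites, at 0.402 (0.287 to 0.564), and POU octamers, at 0.551 (0.472 to 0.643), went the other way. No explanation was tested for these differences.

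The first pattern weighed is the peaks called in 1 library only. On average 70.5% of them touched listed bases of the other library, between the 75% and 50% set in advance, so a calling threshold may account for many of them and stays open. Whole windows were emptied more often than a threshold acting peak by peak gave in shuffles. There were 40 windows of 50000 bp with 8 or more peaks in replicate 1 and none found in replicate 2, and 4 the reverse. At most 5 and 1 arose when found and not found were shuffled among peaks of the same height decile. The lowest decile of replicate 1 ran from 0.0688 to 0.419, and some windows lay within it, such as that of Rbm33 (highest 0.257). For these the shuffle did not compare peaks of like height, so it cannot exclude the threshold. Windows without any peak in the other library held 1.46% and 0.367% of the peaks with no counterpart. Higher neuronal activity in the animal of replicate 1 would need more AP-1 sites in its own distal peaks. Their share was 0.737 (0.692 to 0.785) of that in replicate 2, and 0.791 relative to the reversed consensus. This argues against it for AP-1 sites only, since CRE (1.57, 1.02 to 2.43) and EGR sites (3.94, 1.68 to 9.23) went the other way. So did the immediate early list, with 3 more peaks in replicate 1 (percentile 98.9, and 99.6 at equal numbers of peaks). These sets of distal peaks also differed in G and C (50.5% and 44.4%), so activity as a whole stays open. A higher share of excitatory neurons in replicate 1 cannot be told apart from other causes, because the height ratio at shared distal peaks of excitatory and upper-layer genes, 1.42, was at percentile 83.6 of random lists, with inhibitory (1.53), astrocyte (1.58), oligodendrocyte (1.56) and precursor (1.47) lists also above their random medians. That ratio covered only the 13 of 21 excitatory and upper-layer members with a shared distal peak. It left out Pou3f2, Nrn1, Tbr1 and Fezf2, which had peaks in replicate 1 only, so it cannot decide for these genes.

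The second pattern is the low peak density on X. Fewer genes alone cannot be told apart by the test set in advance. Peaks per gene on X averaged 0.915 of the lowest autosome, chromosome 7, and were within counting error of it in replicate 2. Chromosomes 12 and 18 were compared after the result was seen. They hold 643 genes in 117 Mb and 513 in 87.5 Mb, about as few per Mb as X (948 in 163 Mb). Yet they had 33.7 and 35.4 peaks per Mb in replicate 1 and 28.6 and 29.0 in replicate 2, against 13.9 and 12.7 on X. This argues against fewer genes alone in the comparison with these chromosomes. A promoter test, also added afterwards, argues against it at promoters, where 45.1% of X genes had a peak. The differences from chromosome 7 were -2.51 and -3.11 standard errors. A single copy would lower heights, but X peaks above the X median were 0.512 times as dense as autosomal peaks above 2 times that height, and repeats leave a ratio of 0.479 per Mb of unrepeated sequence, below the lowest autosome in both libraries. Fewer genes and 1 copy together gave 0.747 ± 0.0454 (SD, n = 2), within the range over the libraries of the lower bound of 0.8, so together they may account for it. The kind of genes on X was not tested, and no biological explanation was tested because all animals were male.

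The third pattern is the tallest shared peaks. Of the 100 tallest, 14% had 2 or more copies in the assembly, against 0.827% of all shared peaks, between the bounds set in advance. Split by rank, 80% of the first 10 and 6.67% of ranks 11 to 100 had them. Reads from repeated copies are consistent with the first 10, and they do not account for most of the other 90, of which 95.6% lay at promoters. Copies that the assembly lacks were not counted, and no biological explanation was tested.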
